A study of Mus musculus with 4 samples.

How the data were processed

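RNA sequencing was done on 4 libraries of S-phase neurons from 3-month-old mice carrying L1-GFP, 1 library from each combination of genotype (5xFAD or WT littermate) and fraction (posi or nega). Per the labels, brain and spinal cord were digested, neurons were isolated with a magnetic adult brain dissociation kit, total RNA was taken with a silica column kit, and cDNA was made and amplified with SMART-Seq v4 and tagmented with Nextera XT, a protocol that keeps no strand information. The grouping came from the sample titles. The deposited table lists 55414 genes, of which 980 share their name with another gene and were keyed by identifier, and each was joined to a library by its column header.

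Per the file headers the authors gave 2 values per gene and library, an expected count (an estimated count of reads, with fractions of a read) and TPM, and the deposited table also holds the gene length in bases, the same for every library. Each deposited TPM column sums to 1000000 within rounding. The submitters' processing notes name edgeR 3.26.8 without saying what it was used for. The aligner, the counter, the genome build and the annotation are not given in the sources used here. Of 21144 protein-coding gene symbols compared with GRCm38 positions, 3382 overlapped, so coordinates are quoted as the table gives them with no build named.

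The estimated counts were rounded to whole numbers and normalised by TMM factors over all 4 libraries (edgeR 4.0.16 in R 4.3.3), which were 1.69 for WT posi, 1.13 for WT nega, 0.688 for 5xFAD posi and 0.758 for 5xFAD nega. A gene was measured when 1 library had 20 or more counts, which left 26440 genes. For each of 4 contrasts (posi minus nega in WT and in 5xFAD, 5xFAD minus WT in posi and in nega) the log2 ratio of normalised CPM (the count scaled by the library total and the TMM factor) was computed with a prior count of 2. Genes were counted by a size rule, an absolute log2 ratio of 1 or more, since groups of 1 library allow no p-value, SE or SD. The difference of differences was counted at 2 or more.

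Each fold is the ratio of normalised counts without a prior, and its 95% interval is the exact binomial interval of the split of counts between the libraries. Where a library had 0 counts, the fold was computed against a floor of 3 counts in that library and is given as "at least". The limit of the 95% interval is lower than this value, at log2 7.26 and 7.60 for Acta2 in 5xFAD minus WT in posi and nega. With 1 to 3 counts the interval is given, and no fold is given where both libraries had 3 counts or fewer. Median log2 ratios of all genes were -0.13, 0.06, 0 and -0.06 in the 4 contrasts with TMM, 0, 0.09, 0 and 0 with DESeq2 size factors and 0.28, 0, -1.11 and -0.62 with library size alone.

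Gene lists covered the cell cycle, DNA damage, L1 restriction, innate immunity, amyloid and tau, classes of neurons, glia, immune, vascular and barrier cells, stress, energy metabolism, protein synthesis and sex-linked genes, and 47 had 5 or more measured members. A list's median log2 ratio was set against 10000 random lists of the same size, matched on mean log CPM in 20 bins (seed 11), and stands apart where it lies outside their central 95%. Of 188 list results 70 did so, where chance gives about 9. This describes the 4 libraries and does not test the conditions. Several lists share genes, so their results are not independent. Each median was also computed with members at 0 counts in 1 library at their bound, which is given beside a median in the text where it differed at 2 decimals. The differences between medians and the figure of list medians do not use it.

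The model with fraction and genotype as additive terms used edgeR's quasi-likelihood test, DESeq2 1.42.0 (Wald test) and limma-voom (limma 3.58.1), each with Benjamini-Hochberg adjustment at 0.05. The procedure was tested on simulated data with 25283 genes, of which 200 differed between fractions, where 6.67% of the edgeR calls were genes without a difference. Unchanged simulated genes passed the size rule in the same direction 346 times and in opposite directions 343 times. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

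The contrasts, the size rules, the filters, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named the 8 highest and 8 lowest genes with the same sign in both contrasts of a factor, the 5 highest and 5 lowest of each contrast and of the difference of differences, up to 4 members of each list and contrast by absolute log2 ratio, and the genes of the label checks, not all of which are reported here. It took genes with 100 or more counts in a library of the contrast and left out predicted, unnamed and pseudogene models. Pcna, Tuba1a and the pituitary genes other than Gh and Prl fall outside the rule and were chosen after their values were seen. So were the contrasts in which a gene is given although the rule named it in another, such as Stmn1, Mki67, Sting1, Psap, Xbp1 and Csf1r.

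Alternatives fixed beforehand were DESeq2 size factors, library size alone, prior counts of 10 and 0.5, no filter beyond 1 count, a filter of 100 counts, thinning all libraries to the smallest total and, for the additive model, the other tools. The receptor-gene background (1489 olfactory and vomeronasal receptor genes over 5384.3 kilobases), the figures drawn from it and the restrictions to protein-coding genes, to 100 TMM CPM, to the deposited TPM and to library size alone for lists were chosen after seeing the data. The background share of a library is the mean receptor density (all receptor counts over all receptor length) times the summed gene lengths, divided by the total count. For background subtraction, the density times the gene length was taken from each count, and negative values were set to 0. A gene then at 0 in both libraries of a contrast has a log2 ratio of 0, so a list median of 0 can come from genes with no counts left. Left out were pathway databases, splice forms, L1 and transgene sequence, which a gene table does not give, and raw reads, which were not used here.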

Results

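RNA sequencing measured gene expression in neurons isolated from the brain and spinal cord of 3-month-old mice and taken in S phase, the part of the cell cycle in which DNA is copied. The mice carried L1-GFP, a reporter of new copies of the LINE-1 (L1) retrotransposon, with or without the 5xFAD transgenes. 5xFAD mice express mutant human APP from the Thy1 promoter and serve as a model of amyloid deposition. The 4 libraries form 4 groups of 1 library each, a posi and a nega fraction from WT littermates and a posi and a nega fraction from 5xFAD mice. The titles give posi and nega without a definition, and they are read here, from the study's design, as neurons with and without L1 retrotransposition. How S phase was determined, how many animals made up a library and whether both fractions came from the same animals are not given in the sources used here.

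There were no replicates, so differences are given as ratios between single libraries, with 95% intervals where stated, and no ratio could be set against a spread between animals. The reads came from PCR-amplified cDNA without molecular identifiers, so the intervals and the 3-count floor behind each "at least" value cover counting error only. Library totals differed 6.85-fold, from 1994000 estimated counts in WT posi and 3981135 in WT nega to 12703473 in 5xFAD posi and 13661780 in 5xFAD nega. Genes with a count numbered 31846, 33637, 33036 and 30902 in that order, and genes with 20 or more counts 16871, 18902, 20162 and 19100.

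The libraries also differed in what kinds of gene took the counts. Protein-coding genes took 77.1% of the counts in WT posi, 88.4% in WT nega, 94.7% in 5xFAD posi and 94.4% in 5xFAD nega. Long noncoding RNA genes took 9.14%, 4.85%, 1.5% and 1.80%, and mitochondrially encoded genes 0.995%, 0.518%, 2.81% and 1.04%. The gene with the most counts was Gh, pituitary growth hormone, in WT posi (1.42%), Tuba1a, a tubulin abundant in young neurons, in WT nega (1.58%) and 5xFAD nega (1.84%), and Ttr, the transthyretin that choroid plexus epithelium secretes, in 5xFAD posi (9.82%). Wilson 95% intervals of these shares spanned at most 0.117 percentage points. Across genes, which are not independent replicates, Pearson's r between log CPM values was 0.716 for the 5xFAD pair, 0.499 for the WT pair, 0.620 for the nega pair and 0.381 for the posi pair.

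Olfactory and vomeronasal receptor genes, which brain neurons are not known to use, gave a reference for counts that do not come from their expression. The 1489 receptor genes had 9.79, 8.70, 8.11 and 7.88 counts per kilobase in WT posi, WT nega, 5xFAD posi and 5xFAD nega. Had every listed gene carried this density along its length, such counts would make up 52.2%, 23.2%, 6.79% and 6.14% of each library. These shares rest on the mean. The median density over receptor genes was lower, at 3.05, 3.54, 2.69 and 1.48 in the same order, and 63.7% to 75.9% of them had a count. Of the 958 receptor genes with 20 or more counts in a library, 61.6% to 73.3% passed the 2-fold size rule in each contrast, and their medians were 0.55 and 0.32 (posi minus nega in WT and 5xFAD) and -1.49 and -1.27 (5xFAD minus WT in posi and nega) on the log2 scale.

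**Figure D1:**
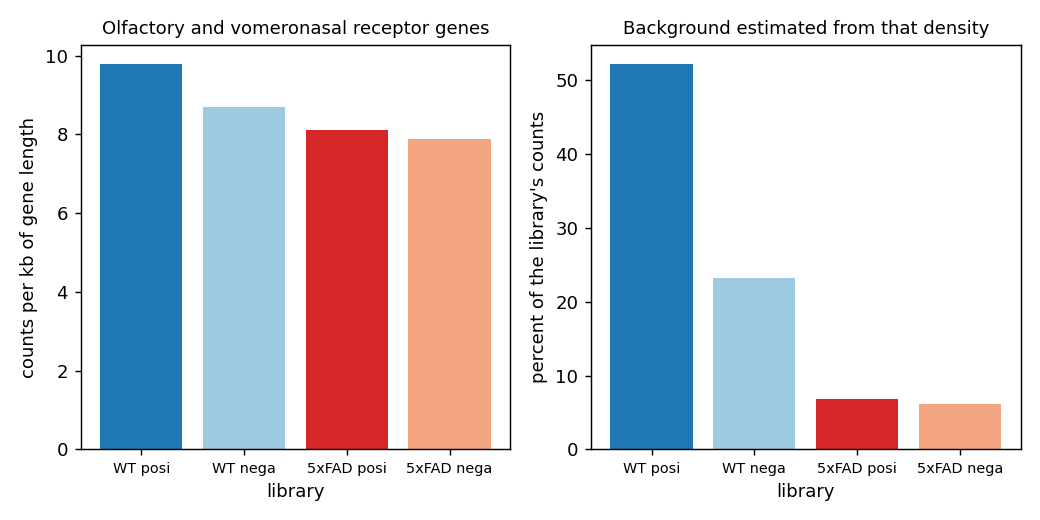
Bars show, for each of the 4 libraries, the mean counts per kilobase of olfactory and vomeronasal receptor genes and the percent of all counts that this density would make up over the listed gene lengths. This mean density was similar (7.88 to 9.79), though the median over receptor genes ran from 1.48 to 3.54. The percent ran from 6.14 in 5xFAD nega to 52.2 in WT posi.

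The label checks covered genes tied to the transgenes and sex-linked genes. App (ENSMUSG00000022892.12, chromosome 16, 84746573 to 84970654, build not given), the amyloid precursor protein gene, was 10.5-fold higher in 5xFAD posi than WT posi and 2.21-fold higher in 5xFAD nega than WT nega, with log2 ratios of 3.40 (interval 3.29 to 3.51) and 1.14 (1.07 to 1.22). Whether reads of the human transgenes were counted under App is not given in the sources used here. Thy1 (ENSMUSG00000032011.6), the endogenous gene whose promoter drives the transgenes, had 15, 42, 188 and 399 counts and log2 ratios of 2.20 and 2.01. The Y-linked genes Ddx3y (58, 128, 542 and 559 counts), Eif2s3y (27, 144, 242 and 538), Kdm5d (50, 64, 254 and 451) and Uty (51, 194, 137 and 31) had counts in all 4 libraries, and Xist, the transcript of the inactive X chromosome, had 40, 6, 0 and 24.

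Posi against nega asks how S-phase neurons with L1 retrotransposition differed from those without. Genes of neuroblasts and immature neurons were lower in posi in both genotypes, and genes of the choroid plexus epithelium, which makes cerebrospinal fluid, were higher. Dcx, a microtubule protein of migrating neuroblasts (chromosome X, 142638838 to 142716307, build not given), was 258-fold lower in posi in WT (log2 -7.82, interval -9.33 to -6.97) and 154-fold lower in 5xFAD (-7.18, -7.73 to -6.83). Dlx2, a transcription factor of interneuron progenitors (chromosome 2, 71373752 to 71377098), had 1051 and 1722 counts in the nega libraries and 0 in both posi libraries, at least 263-fold and at least 484-fold lower. Ttr (ENSMUSG00000061808.5, chromosome 18, 20798337 to 20807378) was 9.23-fold higher in posi in WT (log2 3.21, 3.14 to 3.27) and 8.68-fold higher in 5xFAD (3.12, 3.11 to 3.12), and its level reached 142770 TMM CPM in 5xFAD posi. With 1 library per fraction these are differences between single libraries, and 52.2% of the WT posi counts would be background by the mean receptor-gene density.

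In the gene lists, higher and lower mean a difference of 2-fold or more. All 14 neuroblast genes were lower in posi in both genotypes, with median log2 ratios of -4.72 in WT (-4.63 with genes at 0 counts at their bound) and -4.79 in 5xFAD. Sox4, a transcription factor of early neuronal differentiation, had log2 ratios of -7.60 and -5.08, Stmn1, a tubulin-binding protein, -6.00 and -3.69, and Tubb2b, a tubulin of developing neurons, -3.86 and -6.11. Sp9, a transcription factor of olfactory bulb and striatal interneuron precursors, had 664 counts in WT nega and 0 in WT posi, at least 166-fold lower, and 1776 against 1 in 5xFAD (log2 interval -15.85 to -8.07). Of 17 GABAergic neuron genes, 11 were lower and 3 higher in WT (median -2.10) and 14 lower and 2 higher in 5xFAD (median -3.83). Gad2, which makes GABA, had log2 ratios of -7.39 and -4.06, and Dlx5 -7.23 and -6.12. Pan-neuronal genes had medians of -2.24 in WT (16 of 24 lower, 2 higher) and -1.08 in 5xFAD (12 lower, 3 higher). Among them Tubb3, the neuronal tubulin, had log2 ratios of -7.38 and -4.59 and Stmn3 -7.45 and -2.27. Glutamatergic neuron genes did not stand apart, with medians of 0.15 (-0.06 with the background subtracted) and 0.77.

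Cell division genes were also lower in posi, although both fractions were described as S-phase neurons. Of 51 DNA replication genes, 27 were lower and 5 higher in WT (median -1.19) and 29 lower and 4 higher in 5xFAD (median -1.27). Mcm7, part of the replicative helicase, had 826 counts in WT nega and 0 in WT posi, at least 206-fold lower, and was 34.8-fold lower in 5xFAD. Pcna, the sliding clamp of DNA polymerases, had log2 ratios of -1.19 and -1.30. Of 29 G2 and mitosis genes, 18 were lower and 1 higher in WT (median -1.60), and 27 were lower and 0 higher in 5xFAD (median -2.94). Cdk1, the kinase that drives entry into mitosis, was at least 68.2-fold lower in WT and 5.39-fold lower in 5xFAD, and Tpx2, a spindle protein, had log2 ratios of -5.43 and -6.69. Mki67, the proliferation antigen, went both ways, with 0.82 in WT and -2.54 in 5xFAD. Cytosolic ribosomal protein genes were lower too, 37 of 42 in WT with 1 higher (median -2.25) and 26 of 42 in 5xFAD with 0 higher (median -1.10), for instance Rpl23 (-4.28 and -1.48) and Rps3 (-3.80 and -1.24). Random lists matched to them had medians of -1.0 and -0.24.

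Choroid plexus genes were higher in posi, 9 of 12 in WT with 1 lower (median 2.15) and 12 of 12 in 5xFAD (median 3.47). Folr1, the folate receptor of the choroid plexus, had log2 ratios of 3.17 and 3.51, Kcne2, a potassium channel subunit of its apical membrane, 3.82 and 3.34, and Enpp2, which makes lysophosphatidic acid, 2.35 and 3.69. Aqp1, the water channel of this epithelium, was the 1 gene lower in WT (1 against 69 counts, log2 -4.72, interval -11.02 to -3.17) and was higher in 5xFAD (3.39). Mitochondrially encoded genes stood apart in both genotypes, but by less than 2-fold in WT, where the median was 0.59 and 11 of 13 genes lay within 2-fold (2 higher, 0 lower). In 5xFAD the median was 1.5 (12 of 13 higher, 0 lower). The respiratory chain genes mt-Co1 and mt-Nd5 had log2 ratios of 0.56 and 0.70 in WT and 2.42 each in 5xFAD.

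**Figure D2:**
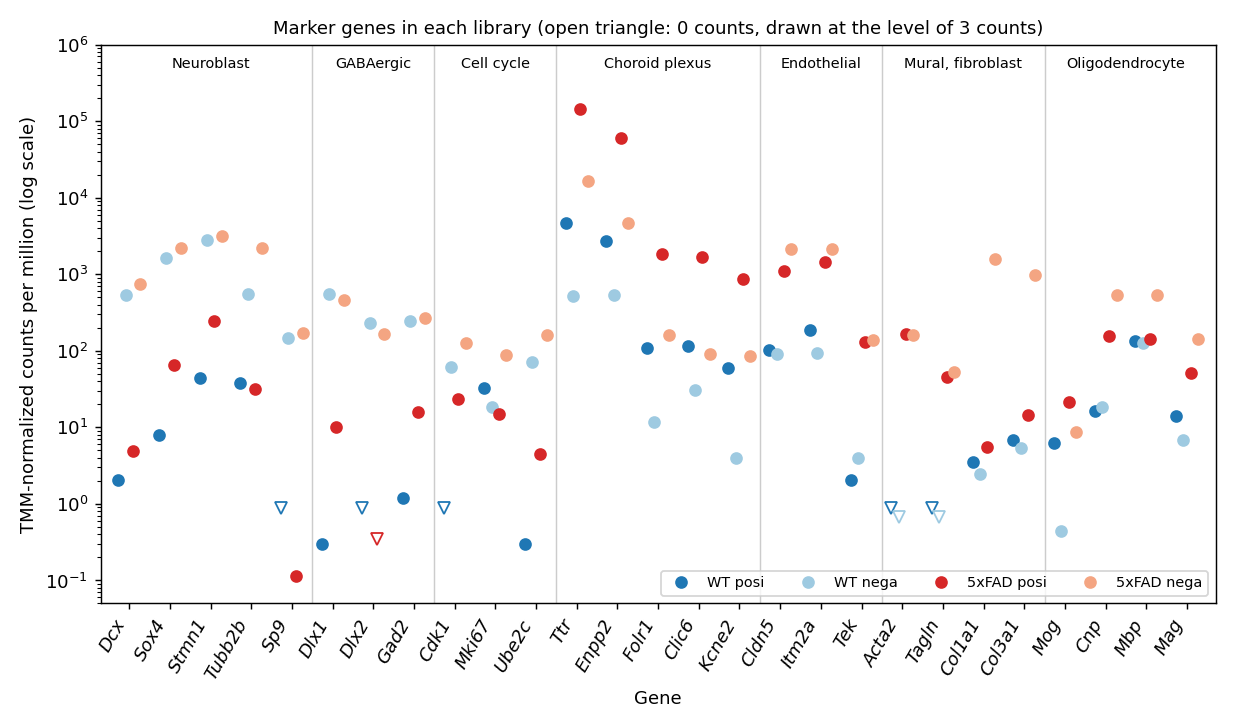
TMM-normalised CPM, the count scaled by library total and TMM factor (log axis), of cell type and cell division genes in the 4 libraries, with open triangles for 0 counts drawn at the level of 3 counts. Dcx lay at 535 in WT nega and 756 in 5xFAD nega against 2.07 and 4.92 in the posi libraries, and Ttr at 4733 and 142770 in the posi libraries against 513 and 16447 in the nega libraries.

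Other lists stood apart from random lists of matched expression in 1 genotype only, a difference between genotypes that was not tested. In WT, nucleic acid sensor genes had a median of 1.02 (6 of 12 higher, 3 lower), with Mavs, the adaptor of the RNA-sensing receptors, 21.9-fold higher. Sting1, the adaptor of cytosolic DNA sensing, was 8-fold higher on 30 against 5 counts (log2 interval 1.62 to 4.72). Endothelial genes had a median of 0.58 in WT (3 of 16 higher, 0 lower), led by Cdh5 (13.9-fold). In 5xFAD, ependymal genes, which build motile cilia, had a median of 2.06 (11 of 13 higher, 0 lower), with Cfap126 at 14.0-fold and Foxj1, the master regulator of motile cilia, at 7.63-fold. Genes of disease-associated microglia had a median of 1.45 (9 of 17 higher, 2 lower), with the lipid carrier Apoe 6.83-fold and the lysosomal protease Ctsd 5.83-fold higher and Spp1, osteopontin, at 132 counts against 0 (at least 52.1-fold). Astrocyte genes had a median of 0.99 (8 of 16 higher, 2 lower), and Acsbg1, an acyl-CoA synthetase, was 13-fold higher. Genes of the unfolded protein and integrated stress responses (median 1.0, 12 of 23 higher, 3 lower) and glycolysis (1.43, 12 of 19 higher, 0 lower) also stood apart on the higher side. Nuclear-encoded oxidative phosphorylation genes did so with a median of 0.43, and 31 of 34 lay within 2-fold. The glycolytic enzyme gene Pgk1 was 3.53-fold higher. With a filter of 100 counts, DNA replication, GABAergic and nucleic acid sensor genes no longer stood apart in WT, nor did astrocyte and ependymal genes in 5xFAD.

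Some lists stood apart on the lower side in 5xFAD and not in WT. L1 restriction and chromatin silencing genes had a similar tally in both genotypes, 14 of 34 lower and 3 higher in 5xFAD (median -0.91) and 13 lower and 1 higher in WT (median -0.62), and stood apart from matched random lists in 5xFAD. Adar, the RNA-editing enzyme, had log2 ratios of -0.96 in WT and -3.27 in 5xFAD, Setdb1, a histone methyltransferase that silences retroelements, -1.58 and -2.50, and Cbx3, a heterochromatin protein, -0.97 and -2.32, while Apobec1, a cytidine deaminase, had -0.16 and 2.61. Neural stem and progenitor genes had a median of -1.52 in 5xFAD (8 of 15 lower, 0 higher), oligodendrocyte precursor genes -1.44 (8 of 13 lower, 1 higher), and lymphocyte genes -1.55 (11 of 18 lower, 1 higher, -1.39 with genes at 0 counts at their bound). Olig1, a transcription factor of the oligodendrocyte lineage, was 13.1-fold lower. Fibroblast and meningeal genes had a median of -1.27 (6 of 11 lower, 3 higher), with the collagen genes Col1a1 280-fold, Col3a1 67.8-fold and Col1a2 53.5-fold lower in posi.

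By single genes, the 8 with the largest ratio of the same sign in both genotypes on the lower side were Dlx2, Mycl, Sp9, Tmem198, Dcx, Rtl6, H2bu2 and Fgd1. Mycl, a MYC family transcription factor, had 0 counts in both posi libraries against 902 and 1668, at least 225-fold and at least 469-fold lower. Tmem198 was at least 80.2-fold and 447-fold lower, Rtl6, a gene derived from a retrotransposon, 150-fold and 267-fold, the histone gene H2bu2 at least 95.4-fold and 121-fold, and Fgd1 at least 33.7-fold and at least 98.4-fold. The 8 on the higher side were Des, Hrh1, Aifm3, Olfr1513, Cep72, Strip2, Olfr1410 and Psd4, of which Olfr1513 and Olfr1410 are receptor genes of the reference set. Des, the muscle intermediate filament desmin, had 104 counts against 3 in WT and 379 against 1 in 5xFAD (log2 intervals 3.94 to 7.83 and 6.32 to 14.12). Hrh1, a histamine receptor, was 39.5-fold and at least 103-fold higher, Aifm3 at least 105-fold and 26.2-fold, Strip2 19.7-fold and 25.4-fold, Cep72, a centrosomal protein, 19.8-fold and 36.3-fold, and Psd4 24.3-fold and 15.7-fold.

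Within WT alone the lowest in posi were Marcksl1, an actin-regulating protein of developing neurons (0 against 7149 counts, at least 1.79e+03-fold), the corepressor Ctbp1 (at least 465-fold), the chaperonin subunit Cct5 (at least 433-fold), the histone gene H2aw (at least 376-fold) and Prmt2 (at least 365-fold). The highest were Aifm3, Pgap6 (298 against 2 counts, log2 interval 5.77 to 10.69), Olfr995 (at least 73.4-fold), B3gnt2 (at least 60-fold) and Olfr313 (at least 52.5-fold). Within 5xFAD the lowest were Rtn2 (at least 617-fold), Dlx2, Mycl, Sema6c (at least 412-fold) and Sp9. The highest were Aldh1l1, an astrocyte enzyme of folate metabolism (1066 against 1 count, log2 interval 7.82 to 15.61), the thioesterase gene Acot11 (at least 298-fold), Mamld1 (at least 288-fold), Igsf1 (at least 279-fold) and the ciliary gene Cfap45 (at least 242-fold).

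Of 26440 genes with 20 or more counts in a library, 15943 (60.3%) differed by 2-fold or more between posi and nega in WT, 6789 higher and 9154 lower, and 14984 (56.7%) in 5xFAD, 8303 higher and 6681 lower. With library size alone as the scaling, more WT genes were higher than lower (55.9% of those past the rule, against 42.6% with TMM), as after thinning to an equal total count (52.6%). Of the genes past the rule in both genotypes, 5619 went the same way (2722 higher and 2897 lower in posi) and 3441 opposite ways, and across genes r was 0.16 and rho 0.18. Which direction was the more frequent depended on the scaling, with 3236 higher and 2657 lower under DESeq2 size factors and 3490 and 2774 under library size alone. Receptor genes went the same way in 185 cases and opposite ways in 191. Among the 4481 genes with 100 or more TMM CPM in a library, 1240 went the same way (247 higher and 993 lower) against 299 opposite, with r of 0.39.

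**Figure D3:**
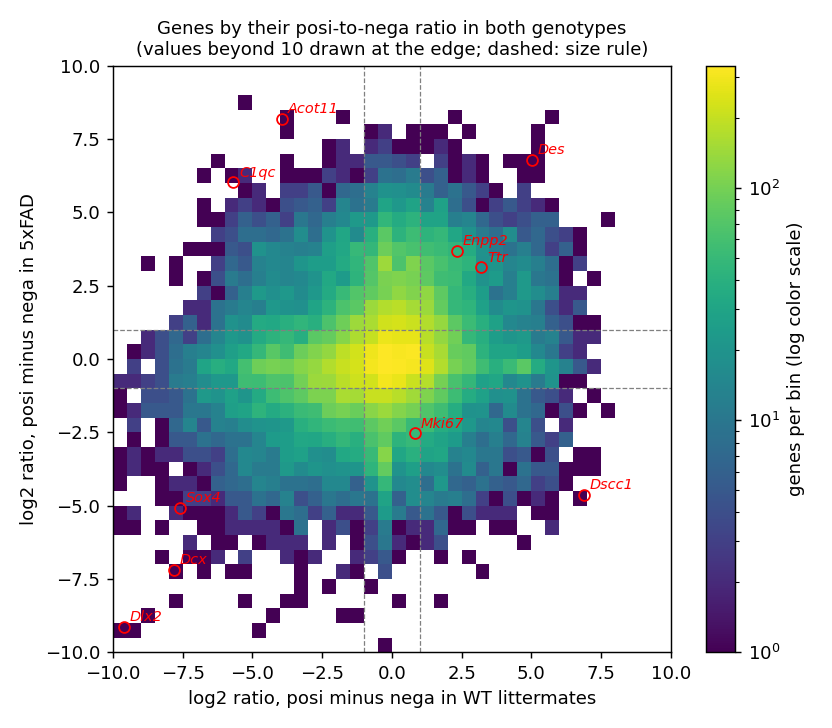
Each bin counts genes (log color scale) by their posi minus nega log2 ratio in WT (x axis) and in 5xFAD (y axis), with dashed lines at 2-fold and 10 genes marked. Dcx, Sox4 and Dlx2 lie low in both genotypes and Ttr and Enpp2 high in both, while r across the 26440 genes was 0.16.

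5xFAD against WT asks how the S-phase neurons of the disease model differed from those of littermates, within each fraction. Genes of blood vessel walls were higher in 5xFAD in both fractions. Acta2, smooth muscle actin (chromosome 19, 34218490 to 34232990, build not given), had 0 counts in both WT libraries against 1459 in 5xFAD posi and 1652 in 5xFAD nega, at least 188-fold and at least 240-fold higher. Cldn5, the tight junction protein of brain endothelium, was 10.7-fold higher in posi (log2 3.42, interval 3.27 to 3.58) and 24.2-fold higher in nega (4.59, 4.45 to 4.74). The collagen gene Col1a1 (chromosome 11, 94827050 to 94843868) was 644-fold higher in nega (log2 9.17, 8.49 to 10.33), with 16281 counts against 11, and had a log2 ratio of 0.62 (-0.27 to 1.70) in posi. Gh (ENSMUSG00000020713.7, chromosome 11, 106191097 to 106192691) went the other way, with 28281 and 1987 counts in WT posi and nega against 6 and 0 in 5xFAD. Both WT libraries had the larger background share by the receptor-gene reference, and each genotype was seen in an unknown number of animals.

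All 16 endothelial genes were higher in 5xFAD in both fractions (medians 3.04 in posi and 3.70 in nega), among them Tek, an angiopoietin receptor (63.5-fold and 34.6-fold), Abcb1a, the P-glycoprotein drug pump (14.8-fold and 110-fold), and Bsg (15-fold and 15.4-fold). Pericyte and smooth muscle genes had medians of 2.21 in posi (10 of 13 higher, 1 lower) and 2.48 in nega (8 higher, 3 lower, 1.95 with genes at 0 counts at their bound). Myl9, a smooth muscle myosin light chain, was at least 143-fold and at least 170-fold higher, Tagln, transgelin, at least 51.7-fold and at least 79.6-fold, and Pdgfrb, the pericyte growth factor receptor, 4.96-fold in posi. Random lists matched to the endothelial genes had medians of 1.62 and 0.63. Fibroblast and meningeal genes stood apart in nega alone (median 5.66, 9 of 11 higher, 1 lower), with Col1a2 289-fold and Col3a1 184-fold higher there, against log2 ratios of 0.43 and 1.05 in posi. In posi this list's median was 1.03 with TMM, -0.24 with library size alone and -0.06 after thinning.

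Choroid plexus genes were higher in 5xFAD in both fractions, 12 of 12 in posi (median 4.18) and 9 of 12 in nega with 0 lower (median 1.90). Ttr was 30.2-fold higher in posi and 32.1-fold higher in nega, and Enpp2 22.3-fold and 8.82-fold. Random lists matched to the choroid plexus genes had medians of 1.66 and 0.65. Ependymal genes had medians of 4.37 (11 of 13 higher, 0 lower, 4.0 with genes at 0 counts at their bound) and 1.86 (10 higher, 0 lower). Oligodendrocyte genes had medians of 2.64 (12 of 16 higher, 0 lower, 1.84 with genes at 0 counts at their bound) and 2.92 (14 higher, 1 lower). Cnp, a myelin enzyme, was 9.66-fold and 28.8-fold higher, and Mag, a myelin-associated glycoprotein, 3.73-fold and 20.5-fold. Genes of disease-associated microglia had medians of 3.70 (12 of 17 higher, 1 lower) and 2.27 (12 higher, 3 lower), and with genes at 0 counts at their bound 3.59 and 2.02. Apoe was 56.5-fold and 14.5-fold higher, and Lgals3, galectin-3, with 0 counts in both WT libraries, at least 45.7-fold and at least 81.1-fold. Genes of homeostatic microglia stood apart in posi alone (median 1.77, 11 of 18 higher, 4 lower, 1.60 with genes at 0 counts at their bound), where Csf1r, the receptor for microglial survival signals, was 6.91-fold higher.

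Housekeeping and stress genes were higher in 5xFAD in both fractions, by more than genes of matched expression, which were higher too. For the 6 lists of this paragraph the medians of the matched random lists lay between 1.01 and 1.76 in posi and between 0.41 and 0.67 in nega, so part of each difference was shared with other expressed genes. Ribosomal protein genes had medians of 2.51 in posi (39 of 42 higher, 0 lower) and 1.32 in nega (35 higher, 0 lower), and nuclear-encoded oxidative phosphorylation genes 3.78 (34 of 34 higher) and 1.67 (27 higher, 0 lower), with Ndufa1, a complex I subunit, at log2 4.35 and 2.43. Lysosome and autophagy genes had medians of 3.23 (20 of 24 higher, 0 lower) and 1.44 (18 higher, 0 lower), with the protease gene Ctsb at 3.59 and 1.89 and Psap at 4.37 and 1.87. Heat shock genes had medians of 3.11 (15 of 17 higher, 0 lower) and 1.38 (11 higher, 0 lower), and the inducible chaperone Hspa1a had log2 ratios of 3.58 and 5.29. Genes of the unfolded protein and integrated stress responses had medians of 3.67 (20 of 23 higher, 1 lower) and 1.25 (16 higher, 1 lower), and Xbp1, the transcription factor of that response, 4.84 and 1.07. Glycolysis genes had medians of 3.13 (16 of 19 higher, 2 lower) and 1.24 (11 higher, 1 lower), with Tpi1 at 6.01 and 3.02.

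Some lists stood apart in 1 fraction only, and the difference between fractions was not tested for these. In posi alone, genes of cell cycle inhibition and senescence (median 2.99, 11 of 17 higher, 3 lower, 2.31 with genes at 0 counts at their bound), of the p53 and DNA damage response (1.88, 18 of 33 higher, 6 lower) and of antioxidant defence and ferroptosis (2.84, 13 of 19 higher, 1 lower) stood apart. Igfbp7, a secreted growth factor binding protein, was 47.6-fold higher, Gadd45b, a DNA damage-inducible gene, had a log2 ratio of 6.37, and Gpx1, glutathione peroxidase, was 31.5-fold higher. In nega alone, interferon-stimulated genes had a median of 1.35 (18 of 32 higher, 7 lower), with Ifitm3 at log2 4.53 and Bst2, tetherin, with 0 counts in both WT libraries, at least 49.0-fold higher. In posi 18 of these were higher and 2 lower, with a median of 1.18 (percentile 97.2 of random lists, and 1.05 with genes at 0 counts at their bound), which was -0.10 with library size alone and 3.60 with the background subtracted, where the list stood apart. Also in nega alone stood NF-kB and inflammatory cytokine genes (2.08, 10 of 15 higher, 3 lower, 1.67 with genes at 0 counts at their bound), MHC class I and antigen processing genes (1.87, 11 of 15 higher, 1 lower), G2 and mitosis genes (0.84, 11 of 29 higher, 2 lower) and histone genes (1.54, 7 of 8 higher, 1 lower). Socs3, a feedback inhibitor of cytokine signalling, was at least 57.2-fold higher, Tap2, a peptide transporter for MHC class I, had a log2 ratio of 4.19, B2m, its light chain, 2.69, and Cdc20, a mitotic regulator, was 4.85-fold higher. Immediate early genes (1.06, 14 of 27 higher, 1 lower), apoptosis genes (1.13, 12 of 21 higher, 2 lower), stem and progenitor genes (1.65, 8 of 15 higher, 2 lower) and mitochondrially encoded genes (1.63, 12 of 13 higher, 0 lower) followed, with Klf2 at 8.39-fold, Casp9 at 10.6-fold and the intermediate filament gene Vim at log2 4.40. Several of these lists had larger medians in posi without standing apart there, namely MHC class I (2.61), mitochondrially encoded (2.75), histone (2.48, or 2.20 with genes at 0 counts at their bound), immediate early (2.21, or 2.02) and apoptosis genes (1.82), while the posi median was -0.86 for G2 and mitosis genes, and 0 with the background subtracted. For NF-kB and inflammatory cytokine genes the posi median was -0.37 and had no settled direction. It was 1.77 with a filter of 100 counts, 0.84 after thinning and 0.06 with the background subtracted. With the background subtracted, apoptosis genes stood apart in posi too (3.59), and antioxidant genes in nega (0.98).

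Ion channel genes of long gene bodies stood apart on the lower side in 5xFAD in both fractions, with medians of -1.38 in posi (11 of 20 lower, 1 higher) and -0.88 in nega (8 lower, 0 higher). Kcnq3, a potassium channel subunit, had log2 ratios of -3.42 and -3.71, Grm5, a glutamate receptor, -2.69 and -2.11, and Scn8a, a sodium channel, -1.96 and -2.05. With the receptor-gene background subtracted, this list no longer stood apart in posi (median -0.03, 8 lower and 5 higher). Genes of spinal cord and brainstem neurons were lower in nega (median -2.50, 10 of 16 lower, 2 higher), where Slc6a4, the serotonin transporter, was 32.6-fold lower and Slc18a3, the vesicular acetylcholine transporter, at least 54.4-fold lower. With the background subtracted, the spinal cord, immediate early and histone lists in nega and the senescence, p53, homeostatic microglia, endothelial, heat shock, glycolysis, antioxidant and ion channel lists in posi no longer stood apart. That standing is relative to matched random lists, and most of the medians themselves stayed large. In posi they were 2.98 for endothelial, 2.90 for heat shock, 2.98 for glycolysis, 3.08 for antioxidant, 2.29 for p53, 3.09 for homeostatic microglia and 2.39 for senescence genes. In nega they were 1.97 for histone, 0.81 for immediate early and -1.04 for spinal cord genes. With a filter of 100 counts, the p53, homeostatic microglia, oligodendrocyte and pericyte lists in posi and the G2 and mitosis, ependymal and immediate early lists in nega no longer stood apart.

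**Figure D4:**
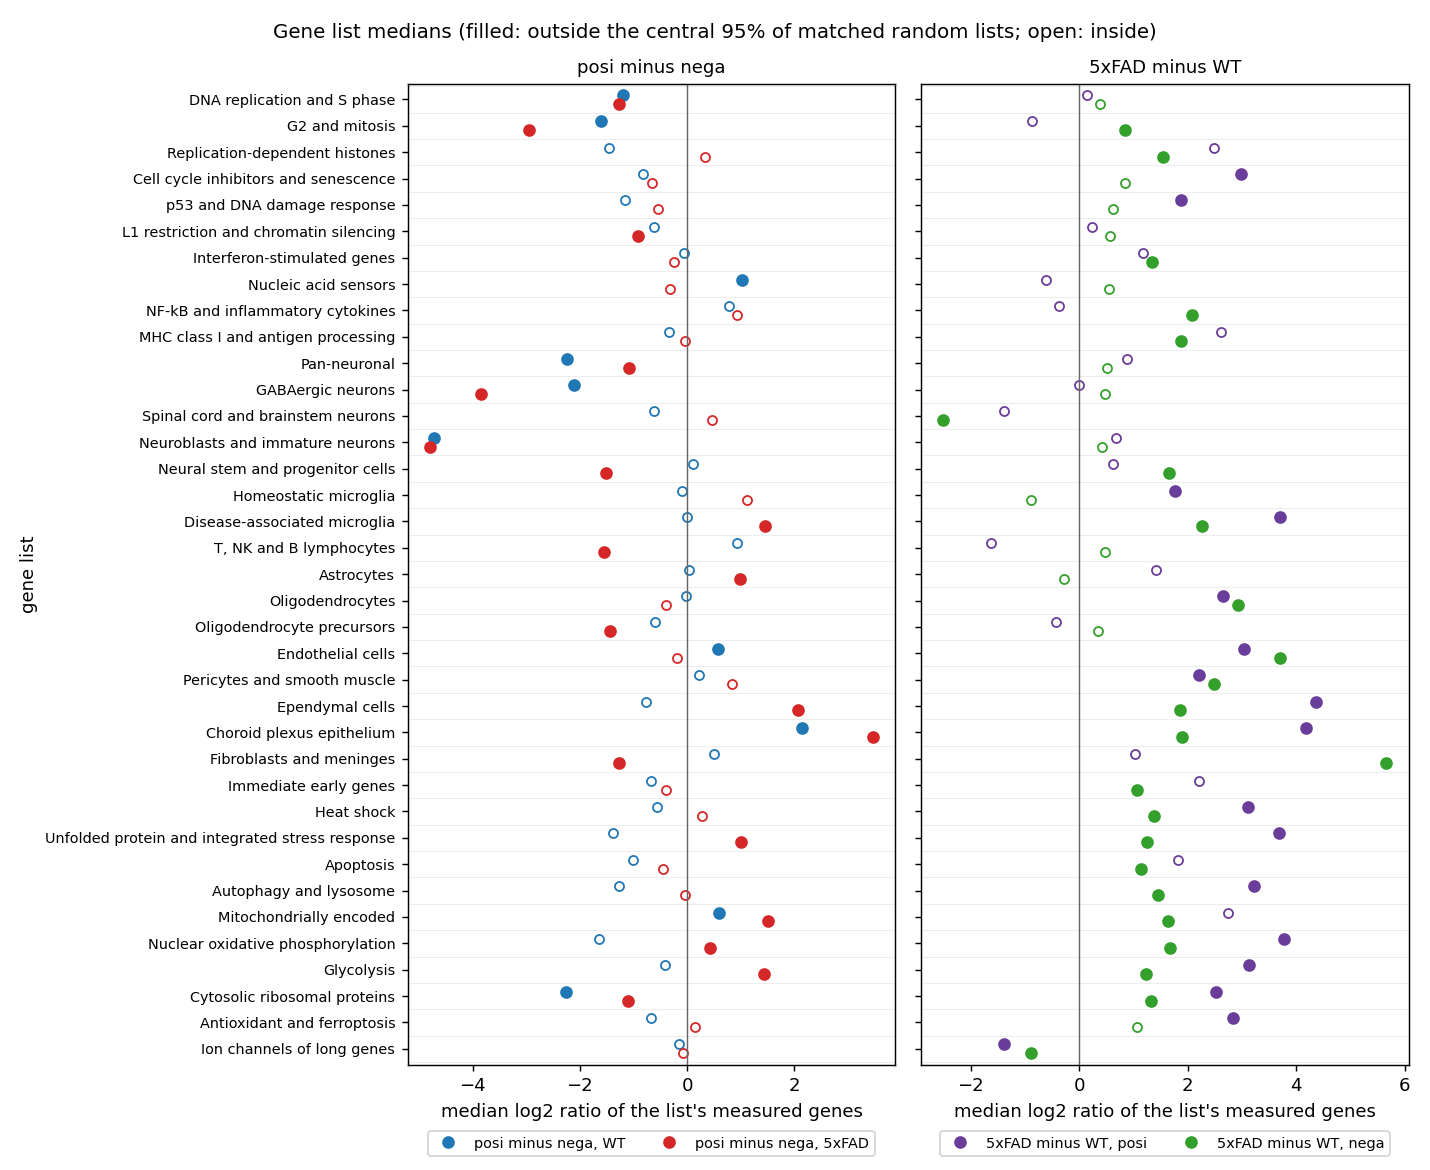
Points show the median log2 ratio of each gene list that stood apart in at least 1 contrast, for posi minus nega in WT and 5xFAD and for 5xFAD minus WT in posi and nega, filled where the median lay outside the central 95% of random lists matched on expression. Neuroblast genes lay at -4.72 and -4.79 for posi minus nega, and endothelial genes at 3.04 and 3.70 for 5xFAD minus WT.

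The 8 genes with the largest ratio of the same sign in both fractions on the higher side were Acta2, Myl9, Elovl7, Thbs2, Capg, Lama5, Tagln and Cck. Elovl7, a fatty acid elongase, had 1 count in each WT library against 2169 and 1035 (log2 intervals 7.23 to 15.02 and 6.33 to 14.12). Thbs2, thrombospondin 2, was at least 59.4-fold and at least 98.9-fold higher, the actin-capping gene Capg at least 56.6-fold and at least 95-fold, the laminin gene Lama5 at least 110-fold and at least 70.2-fold, and Cck, a neuropeptide, at least 144-fold and at least 68.5-fold. On the lower side were Gh (1.22e+04-fold and at least 1.52e+03-fold), Rmi2 (62.9-fold and at least 78.9-fold), Usp17lc, Aoc1 (23.6-fold and at least 113-fold), Grm2, a presynaptic glutamate receptor (39.0-fold and 21.7-fold), AI463229 (19.0-fold and at least 149-fold), Tspan18 (18.4-fold and 42.0-fold) and Nlrc3. Usp17lc had 103 and 168 counts in WT against 2 and 10 in 5xFAD, and Nlrc3 256 and 154 against 42 and 2, with log2 intervals of -10.12 to -5.17 for Usp17lc in posi and -10.53 to -5.59 for Nlrc3 in nega.

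In posi alone the highest in 5xFAD were Ace, the angiotensin-converting enzyme (0 against 6001 counts, at least 773-fold), Epn3 (at least 562-fold), Acadvl, an enzyme of fatty acid oxidation (at least 551-fold), Cct5 (at least 412-fold) and the proteasome gene Psmc5 (at least 365-fold). The lowest were Prl, prolactin (ENSMUSG00000021342.15, chromosome 13, 27241553 to 27249188), with 17144 counts in WT against 2 (log2 interval -17.48 to -12.58), Gh, Npas4, an activity-induced transcription factor (at least 161-fold), Pudp (at least 141-fold) and Shisa7 (at least 135-fold). In nega alone the highest were Col1a1, Pcolce, which aids collagen maturation (at least 592-fold), Acta2, Osr2 (at least 224-fold) and Mfap4 (at least 210-fold), and the lowest Gh, the protocadherin genes Pcdhga6 (at least 270-fold) and Pcdha3 (at least 232-fold), the noradrenaline transporter gene Slc6a2 (at least 203-fold) and Plag1 (at least 192-fold).

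Of the 26440 genes, 19097 (72.2%) differed by 2-fold or more between genotypes in posi, 9890 higher and 9207 lower in 5xFAD, and 16389 (62.0%) in nega, 7174 higher and 9215 lower. With library size alone, 33.5% and 30.2% of those past the rule were higher, against 51.8% and 43.8% with TMM, and that scaling put the median of all genes at -1.11 and -0.62. The same direction in both fractions was seen for 9434 genes (4384 higher and 5050 lower in 5xFAD) and opposite directions for 2670, with r of 0.37 and rho of 0.41 across genes. The balance of directions depended on the processing, with 2266 higher and 8300 lower under library size alone, 1626 and 8339 with the deposited TPM, and 4469 and 3498 with the background subtracted. Receptor genes went the same way in 349 cases and opposite ways in 142. Of the 5050 genes lower in both fractions 73.1% lay inside the density range of receptor genes in both WT libraries and 39.8% were protein-coding. Of the 4384 higher, 14.7% lay inside that range in both 5xFAD libraries and 88.2% were protein-coding. The shares inside the range were thus taken in different libraries, for each set those in which it was the higher, and are not a like comparison. Among genes with 100 or more TMM CPM in a library, 1927 went the same way (1752 higher and 175 lower) and 86 opposite ways.

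The difference of differences asks whether the gap between fractions depended on genotype. It reached an absolute log2 value of 2 in 12497 genes, 7985 with the larger posi minus nega ratio in 5xFAD and 4512 with the smaller, and was not tested. That balance also depended on the scaling, with 6150 and 6205 under library size alone and 4491 and 5069 with the deposited TPM. App had a posi minus nega log2 ratio of -1.0 in WT (interval -1.12 to -0.87) and 1.26 in 5xFAD (1.22 to 1.29), and Mki67 had 0.82 (0.40 to 1.26) and -2.54 (-2.84 to -2.30). Lrrc3b had 45 and 0 counts in WT posi and nega against 0 and 164 in 5xFAD, and Acot11 had 3 and 80 against 755 and 0.

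An additive model of fraction and genotype, which takes the difference of differences as error with 1 residual degree of freedom, called 0 genes for either factor by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Dlx2, Mycl and Sp9 shared the smallest adjusted p for fraction in that quasi-likelihood test of edgeR (0.144 after Benjamini-Hochberg adjustment). For genotype the smallest was 0.212 by the same test and adjustment, shared by genes that included Acta2, Epn3 and Myl9. At an unadjusted p under 0.05 there were 1261 genes for fraction and 2533 for genotype, where chance alone gives 1322. DESeq2 called 383 and 1860 genes, and limma-voom 96 and 111. On simulated data with 8-fold differences the edgeR fit called 95% of the differing genes, and with 2-fold differences 3%, at a dispersion of 0.1 that lay below the 0.928 estimated from these libraries.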

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

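All tests of the fraction pattern and of the vascular pattern were chosen after the result was seen, and the tests of the genes lower in 5xFAD were written before theirs, apart from those said below to be added later. The results below were picked out because the effect of 1 factor had opposite signs at the levels of the other, and none of these differences was tested, since each group has 1 library. A fitted difference of differences that rests on 0 counts depends on the prior count and is no bound.

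G2 and mitosis genes had a median 5xFAD minus WT log2 ratio in posi minus that in nega of -1.70. The same quantity was -1.16 for nucleic acid sensor genes and 2.66 for homeostatic microglia genes. For posi minus nega, the median in 5xFAD minus that in WT was -2.48 for lymphocyte genes, 2.82 for ependymal genes, -1.77 for fibroblast and meningeal genes and 2.39 for genes of the unfolded protein and integrated stress responses. With the background subtracted the signs were no longer opposite for 4 of these lists, each with 1 median of 0. Since the subtraction sets low counts to 0, such a median can come from genes with no counts left. It leaves the direction unsettled and does not show equal expression. G2 and mitosis genes then had medians of 0 in posi (10 higher, 8 lower) and 0.80 in nega, homeostatic microglia genes 3.09 and 0, ependymal genes 0 in WT and 2.43 in 5xFAD, and fibroblast and meningeal genes 0 and -2.96. With library size alone the nega median of nucleic acid sensor genes was -0.01.

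Acot11 had a difference of differences of 12.12, C1qc, a complement subunit made by microglia, 11.70 (0, 67, 166 and 0 counts in WT posi, WT nega, 5xFAD posi and 5xFAD nega), the protocadherin gene Pcdhga11 11.60 (0, 508, 409 and 57), Eno4 11.11 (0, 14, 495 and 0) and the histone demethylase gene Kdm4d 11.04 (0, 122, 153 and 5). Dscc1, a replication factor, had -11.54 (118, 0, 0 and 74), Lrrc3b -11.29, Mfsd4b4 -11.28 (49, 0, 0 and 150), Pramel36 -11.16 (52, 0, 0 and 130), Pcdhac2 -10.21 (21, 2, 0 and 410) and Prl -9.34 (17144, 3998, 2 and 615).

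Choroid plexus genes were higher and neuroblast genes lower in posi in both genotypes. On a lower yield of the posi libraries, the neuroblast median lay below that of ribosomal protein genes by a log2 gap of -2.47 in WT and -3.69 in 5xFAD. The bootstrap intervals were -3.92 to -1.61, which excludes 0 but not the gap of 2 set for the test, and -4.36 to -2.79. The 2 lists thus did not fall equally. This cannot decide on the yield, because the neuroblast list was picked for being low in these libraries. Ribosomal protein genes were themselves lower in posi. For a single neuronal population diluted by choroid plexus cells, the gap to glutamatergic genes was -4.87 in WT (-6.55 to -3.97) and -5.56 in 5xFAD (-6.59 to -4.46). It cannot decide this either, because the glutamatergic medians (0.15 and 0.77) were above 0, as were those of receptor genes (0.55 and 0.32). Genes at background would not follow a dilution of neuronal RNA. Choroid plexus cells or their RNA in the posi fraction stay open for the choroid plexus part, since no test here decided it. That 9 of the 12 markers were 2-fold or more higher in the genotype with fewer restates the pattern, Aqp1 went the other way in WT, and the neuron isolation step should remove such cells. A difference between reporter fractions in the neurons themselves stays open with 1 library per group.

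Genes lower in 5xFAD than in WT in both fractions numbered 5050. Genomic DNA counted in genes stays open as a cause, as 73.1% lay inside the receptor-gene density range in both WT libraries. That is between the 80% set in advance for this cause and the 50% set against it. The range ran from 0 to 58.6 counts per kilobase in WT posi and from 0 to 53.3 in WT nega. Weakly expressed genes fall inside it too, and the share over all measured genes was not computed, so the 73.1% does not point to genomic DNA. A genotype effect stays open too, since with the background subtracted 3498 genes were lower in both fractions, against 2628 that went opposite ways. Of the 5050, in a count added after the result was seen, 3240 were still lower in both, 7 went opposite ways, 1 was higher in both and 1131 were no longer measured, in the same libraries that picked them. In a comparison also added later, their median unscaled log2 ratio was -1.09 in posi and -1.87 in nega, where all 958 measured receptor genes had -0.22 and -0.20. The 327 receptor genes that were lower in both fractions by the same rule had -1.31 (bootstrap interval -1.58 to -1.03) and -1.71 (-2.15 to -1.47), so the larger drop does not exclude background. The explanations cannot be told apart for these genes, because the larger background share and the WT genotype fall on the same libraries.

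Vascular, mural and fibroblast genes were higher in 5xFAD nega than WT nega. Lower depth of the WT libraries is argued against, as the lowest of the 3 list medians was 2.91 after all libraries were thinned to the smallest. On a general loss of transcripts in the WT libraries, the median over all 40 measured members was 3.81. Random genes matched on their level in 5xFAD nega had 0.80 (0.44 to 1.15), so these members differed by more than matched genes. That comparison cannot decide on a general loss, because the 3 lists were picked for standing apart from matched random lists in this contrast. These tests replaced earlier ones on the 35 members with 10 or more TMM CPM in 5xFAD nega, of which 6 (17.1%) had 3 counts or fewer in WT nega, against 1.67% of matched genes (upper bound 5.71%). A genotype effect stays open with 1 library per group, as does a difference in how many vessel cells each preparation carried, which was not tested, although the neuron isolation step should remove such cells.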

How the results depend on the processing

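Protein-coding genes only, background subtraction, deposited TPM, 100 TMM CPM and library size alone for lists were chosen after seeing the data. With a filter of 100 counts the size rule counted 9546 and 8024 genes for posi minus nega in WT and 5xFAD, 11267 and 8175 for 5xFAD minus WT in posi and nega, 3504 and 5192 in the same direction and 6354 for the difference of differences, with fewer genes tested. Protein-coding genes only gave 9249 for posi minus nega in 5xFAD, 12502 and 9519 for genotype, 5657 genotype genes in the same direction and 7558 for the difference of differences, again with fewer genes. At 100 TMM CPM 1240 and 1927 genes went the same way. The additive model called 383 and 1860 genes with DESeq2, 96 and 111 with limma-voom and 15 and 149 with edgeR and no filter, and 0 with DESeq2 size factors or 100 counts in edgeR (the cause was not tested).

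The totals of the 62 other summary counts stayed within 1.5 times, but their parts by direction moved further in places. Thinning gave 2226 fraction and 1463 genotype genes with opposite signs, 4680 higher in 5xFAD in nega and 4759 on the larger side of the difference of differences, and a prior of 10 gave 1728 genotype genes with opposite signs. Protein-coding genes only gave 6056 lower in posi in WT and 1949 fraction genes with opposite signs, no filter gave 10365 and 12562 higher in posi, and the deposited TPM gave 5585 and 3895 higher in 5xFAD, besides the splits given with the results. Of 188 list results, 168 had a value with 100 counts and 184 with background subtraction. Among the results with no value, histone and spinal cord genes (genotype, nega) and lymphocyte genes (5xFAD) had stood apart and could not be followed to 100 counts. Of those with a value, 12 lost their standing with 100 counts, 12 with background subtraction, 9 with thinning, 4 with a prior of 10 and 0 with other scalings, and no list that stood apart changed sign where it had a value. Others came to stand apart, 2 with 100 counts, 8 with background subtraction, 9 with thinning, 4 with a prior of 10 and 2 with library size alone. Those that lost it under more than 1 alternative were nucleic acid sensors, GABAergic genes (WT), oligodendrocyte, homeostatic microglia and p53 genes (genotype, posi), and G2, spinal cord and immediate early genes (genotype, nega), and S phase genes in WT lost it with 100 counts (-0.74). WT posi is the library most in doubt, and the contrasts without it are posi minus nega in 5xFAD and genotype in nega. No pairing by animal could be set because no label says which fractions shared animals, although the additive model compares the fractions within each genotype. No other split of the samples exists with groups of 1. Depth limits WT posi most, where 0 counts allow up to 3.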

Other observations

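The test of the pituitary hypothesis was written after several pituitary counts were seen, and its resampled spread was added after its result. Lists that stood apart in no contrast with the settings chosen first also hold biology. Among amyloid and tau genes, with medians of -0.75 and 0.04 (-0.10 with library size alone) for posi minus nega in WT and 5xFAD and 1.69 and 0.81 for 5xFAD minus WT in posi and nega, Clu, an amyloid-binding chaperone, was higher in 5xFAD with log2 ratios of 5.43 and 5.14, and Apbb1, an APP-binding adaptor, with 8.57 and 1.13. Reactive astrocyte genes had medians of 0.22, 0.35, 1.55 and 0.91 in the same order, the first and last 0.10 and 0.50 with genes at 0 counts at their bound. The last stood apart with the background subtracted (1.98, 7 of 13 higher, 3 lower). Gfap, a member of this list given after its values were seen, went the other way, with 5xFAD minus WT log2 ratios of -1.78 in posi and -2.91 in nega. Cholesterol synthesis genes had medians of -1.43, -0.28, 1.85 and 0.95, with Dhcr7, the last enzyme of that synthesis, 9.46-fold and 8.84-fold higher in 5xFAD. Erythroid genes had medians of -1.05, -1.07, 1.28 (-0.02 with library size alone) and 0.88, and the globin gene Hba-a1 had 4624, 9680, 31296 and 81542 counts in WT posi, WT nega, 5xFAD posi and 5xFAD nega.

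Glutamatergic genes had genotype medians of 0.38 in posi (-0.80 with library size alone) and -0.27 in nega, though Slc17a7, a vesicular glutamate transporter, was 9.52-fold and 2.30-fold higher in 5xFAD. With the background subtracted the nega median of the list was 1.88 and it stood apart. Striatal and cerebellar genes had medians of 0.39, 0.42, 0.20 and -0.23. The second was -0.05 with the background subtracted, the third -0.43 with library size alone and the last -0.13 with genes at 0 counts at their bound. Their median in the WT fraction contrast has no settled direction, since it was -0.41 with genes at 0 counts at their bound, -2.51 with a filter of 100 counts and -3.64 with the background subtracted, where 8 of 12 were lower and the list stood apart. Synaptic genes had -0.59, -0.26, 0.34 and 0.44, the last pair -0.93 and -0.13 with library size alone. Border macrophage and monocyte genes had -0.48, 0.61, 0.31 and -0.12 (1.58 with the background subtracted), neutrophil genes 0.00, 1.05, 0.39 and -3.23 over 5 measured members (the third -0.88 with library size alone and -0.47 after thinning, the last 0 with the background subtracted), and sex-linked genes -0.33, -0.19, 0.51 and 0.69, and with library size alone the WT fraction and posi genotype medians of the macrophage and sex-linked lists changed sign.

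Gh and Prl were abundant in the WT libraries, at 8372 and 5075 TMM CPM in WT posi. Pituitary cells or their RNA in the WT libraries may be a source, on the hypothesis that other pituitary genes would then be higher in WT as well. In posi, 13 other pituitary genes had a median WT over 5xFAD log2 ratio of 1.55 (bootstrap interval 0.42 to 2.94). That lay at percentile 94.6 of matched random lists (57.8 to 100 at the interval's ends). By the rule written for the test, a percentile inside the central 95% counts against this source. The question is left open only because the spread added later reached beyond that range. Receptor genes, which stand for background, had a 5xFAD minus WT median of -1.49 in posi, close to the same size. Ghrhr, the receptor for growth hormone-releasing hormone, had 65, 33, 0 and 0 counts in WT posi, WT nega, 5xFAD posi and 5xFAD nega, Tshb 234, 244, 205 and 45, Pomc 44, 1, 26 and 603, and Pou1f1, the transcription factor of hormone-producing cells, 39, 37, 48 and 50. The 3 of the 13 that went the other way in posi were Chga (1, 162, 669 and 795 counts, log2 7.02 for 5xFAD minus WT in posi), Cyb561 (129, 215, 9715 and 1430, log2 4.85) and Scg2 (373, 200, 1670 and 2658, log2 0.79). Of the 13 genes Scg2 and Drd2 are also in neuronal lists, and the neuron isolation step should remove pituitary cells.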
